A study of Mus musculus with 6 samples.

How the data were processed

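Gene expression was measured by RNA sequencing in 6 libraries labelled as mouse dental epithelial cells, 3 control and 3 Pkm cKO. Per the labels' protocols, RNA was extracted with a column kit and 200 ng of total RNA went into a universal RNA-seq library kit. The authors deposited 1 table of whole-number read counts per gene for all 6 libraries, with gene symbols, NCBI gene numbers and annotation terms. Per the submitters' processing notes, fastp, HISAT2 and the mouse build mm39 were used. The counting program, its strand setting, the gene annotation and all versions are not given in the sources used here. The genome reference at hand was of another build, so it was used only to match gene names and no coordinates are given. Reads of a gene and an antisense partner, of overlapping genes, and of near-identical copies therefore cannot be told apart. Some abundant housekeeping genes had few counts, such as Gapdh (107 CPM in controls), Aldoa (6.77 CPM) and the mitochondrial gene COX2 (49.0 CPM, against 5884 CPM for COX1), and their levels are uncertain because reads shared with other genes may have been left out. These 4 genes were picked after their values were seen.

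Groups and replicate numbers were taken from the labels, which call the samples biological replicates and do not say whether each came from 1 animal or from pooled tissue. The p-values measure the spread between these samples. Total counts were 30588350 to 39415700, so for genes with many reads counting error was small beside the spread between libraries, whose biological coefficient of variation was 0.300. For tested genes with few reads in a group it was not small. No libraries were duplicates: the chi-square per gene between any pair was at least 28.5. All per-sample columns of the table were used.

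From the deposited counts, genes were kept by edgeR's filterByExpr, libraries were scaled by the TMM method, and the groups were compared with edgeR's quasi-likelihood test (glmQLFit with robust estimation, edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are cKO minus control, and SE is the fold change divided by the square root of F. CPM values use the scaled library sizes. Correlations and principal components used log2 CPM with a prior count of 2. The median log2 fold change of all tested genes was 0.0068.

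Before the data were examined, 47 gene lists were fixed, covering metabolism, stress, tooth development, signaling, proliferation, epithelium and other cell types. Of their 873 entries, 861 were found in the table, 23 of them under another name. The 46 lists other than that of sex-linked genes were tested if they had at least 5 measured members. The test was limma's camera (limma 3.58.1) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists, with an estimated correlation, ranks and fry as alternatives. Camera compares a list with all other genes, and fry does not. The text named Pkm and Pklr, then the 10 highest and 10 lowest fold changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM, groups that did not overlap, a protein-coding type and an ordinary symbol (71 genes qualified). It also named up to 4 members of a list with the lowest p and, for lists of other cell types, up to 3 members with the highest mean CPM. Genes outside this rule are said to be so where they appear. Of the genes that fell under it, 2 were kept in all fits and list tests but are not reported singly here.

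Alternatives fixed before the data were examined were DESeq2 size factors or upper-quartile scaling in edgeR, no filter beyond 1 read, at least 1 CPM in 3 samples, leaving out each library in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, edgeR without robust estimation, and removal of mitochondrial, hemoglobin and sex-linked genes. Sample quality weights in limma-voom and tests of the table's own GO terms and KEGG pathways were added after the data were seen. The procedures were tested on simulated counts with the means, library sizes and dispersions of the real genes. For Pkm cKO against control, 200 of 15690 tested genes were changed 2-fold or 4-fold, and a list of 20 further genes was raised 1.5-fold. In these counts edgeR recovered 45% of genes changed 2-fold and 86% of genes changed 4-fold, and 8.33% of its calls were false. DESeq2 recovered 60% and 93% with 20.4% of its calls false, and limma-voom 32% and 78% with 5.98% false. A simulated list of 20 genes raised 1.5-fold had a camera p of 2.6e-10, while 1.5% of 200 lists without change had a p under 0.05. With an estimated correlation the same list had a p of 0.0455, and 0% of the lists without change had a p under 0.05. The simulation drew genes independently, so it does not test camera's preset correlation. It also gave both groups the same dispersion for a gene, whereas the real cKO libraries correlated less with each other than the controls did. The shares recovered and false may therefore not hold for the real libraries.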

Results

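RNA from samples labelled as mouse dental epithelial cells was sequenced at postnatal day 0. The dental epithelium is the layer of the developing tooth whose cells become the enamel-secreting ameloblasts. Mesenchymal transcripts were also abundant in both groups, as given below. The 6 libraries fell into 3 controls, labelled wild type, and 3 from mice with a conditional knockout of Pkm (Pkm cKO), the gene of the M-type pyruvate kinases that carry out the last step of glycolysis. The series asks how loss of Pkm alters gene expression in the dental epithelium while teeth form. Total counts were 38130829, 38888685 and 39415700 in control replicates 1 to 3, and 30588350, 33716938 and 39085792 in Pkm cKO replicates 1 to 3. Of 24959 genes in the table, 15930 had enough reads to be tested. Across these genes the log2 CPM (read counts scaled to a common library size) of the controls correlated with each other at r = 0.981 to 0.986, and those of the cKO libraries at r = 0.944 to 0.966. Pairs from different groups ranged from 0.918 to 0.969, so the cKO libraries were about as far from each other as from the controls. The first principal component held 51.3% of the variance and placed Pkm cKO replicate 3 at 93.2, against 5.13 and 19.1 for the other cKO libraries and -52.2 to -25.3 for the controls.

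Pkm itself was measured first, since it checks the labels. It stood at 1281, 1185 and 1049 CPM in the controls and at 309, 395 and 350 CPM in the cKO libraries. The mean fell from 1172 ± 117 to 351 ± 43.0 CPM (SD, n = 3 each), a log2 fold change of -1.74 (SE 0.159) or 3.33 times lower, with an edgeR quasi-likelihood adjusted p of 0.0109. The groups did not overlap in any library, and no cKO library was without Pkm reads. The deleted exon and the Cre driver are not given in the sources used here, so these reads were not assigned to undeleted cells or to a transcript that is still made. Pklr, which encodes the liver and red-cell pyruvate kinase, had at most 10 reads in a library and was too low to test. The edgeR adjusted p of Pkm rose to 0.0792, 0.0600 and 0.0790 without control replicates 1, 2 and 3, and it was 0.0677 when a change of at least 1.5-fold was required.

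**Figure D1:**
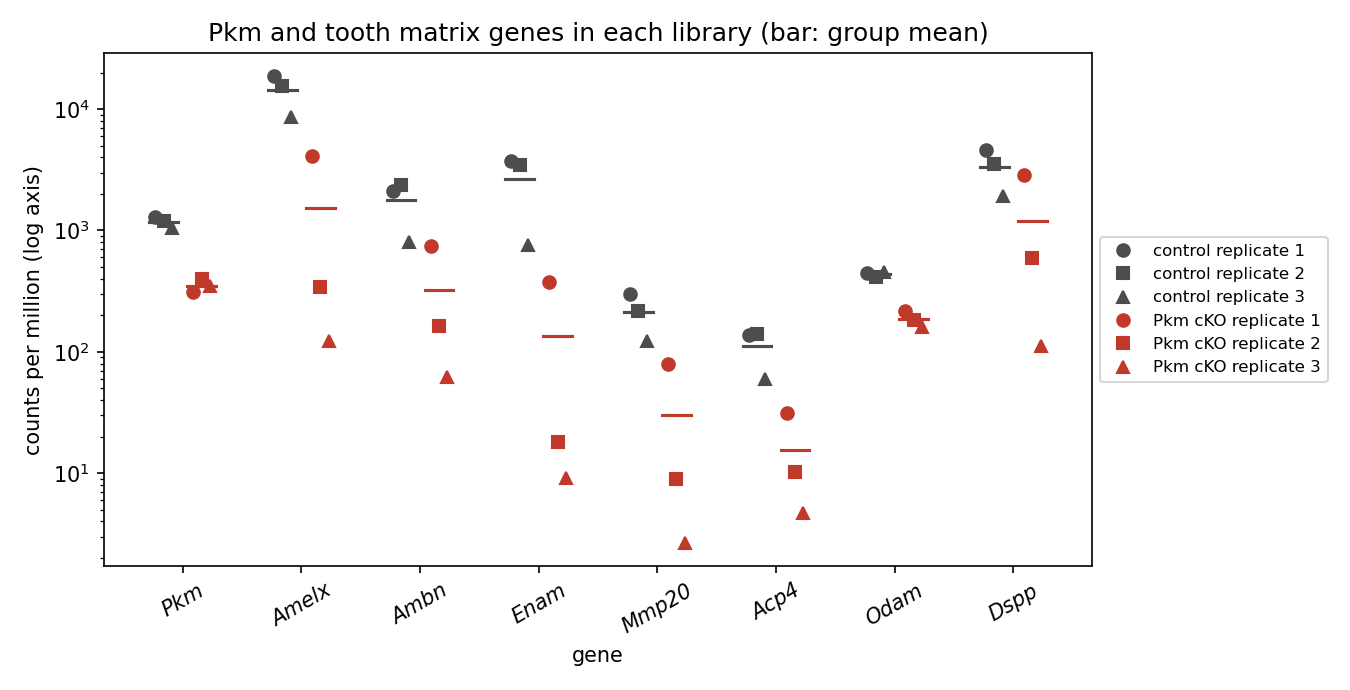
CPM (log axis) of Pkm, of 6 genes of the enamel list and of Dspp in each library, with control libraries in grey, Pkm cKO libraries in red, a marker shape per replicate number and a bar at each group mean. Pkm lay between 1049 and 1281 CPM in controls and between 309 and 395 CPM in cKO libraries, and Amelx spread from 4136 to 122 CPM within the cKO group.

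Between the groups, 88 genes differed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 55 were higher and 33 lower in the cKO libraries. All 88 had groups that did not overlap, and 80 changed at least 2-fold. Of all 15930 tested genes, 3716 (23.3%) had groups that did not overlap, where 10% would be expected by chance for 3 against 3. The 10 highest and 10 lowest genes given here are those that met the naming rule, and some called genes outside it changed more. Among the higher genes that met it, Ptgfr, the prostaglandin F receptor, came first. It stood at 2.75 ± 0.679 CPM in controls and 26.7 ± 17.1 CPM in cKO libraries (log2 fold change 3.28, SE 0.503, edgeR adjusted p 0.0487). Genes of the extracellular matrix and of its turnover were among the 10 highest: Col8a2 (log2 fold change 2.49, SE 0.391) and Col13a1 (2.17, SE 0.288) encode collagens, and Htra4 (2.11, SE 0.348) encodes a secreted serine protease. Crispld2, a secreted protein, rose with a log2 fold change of 2.38 (SE 0.369). The same end of the ranking held Aldh1a2 (2.31, SE 0.341), the main retinoic acid-producing enzyme of the embryo, and Cxcl12 (2.10, SE 0.340), a chemokine typical of stromal cells. Kcne4, a potassium channel subunit, the dipeptidase gene Dpep1 and the adrenergic receptor gene Adra2a completed the 10 highest, with log2 fold changes of 2.56, 2.39 and 2.20.

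The 10 lowest genes by the same rule held Pkm and ranged from Aldh1a7 (log2 fold change -2.38, SE 0.429), an aldehyde dehydrogenase, to the beta-globin gene Hbb-bt (-1.35, SE 0.220). Manf, a protein of the endoplasmic reticulum that responds to folding stress, fell from 391.6 ± 106 to 151 ± 28.9 CPM (log2 fold change -1.38, SE 0.223, edgeR adjusted p 0.0444). Fam3c, which encodes a secreted protein, fell from 199 ± 31.4 to 73.5 ± 14.6 CPM, and Cntnap2, a neurexin-family adhesion molecule, from 94.6 ± 14.8 to 29.4 ± 3.68 CPM. Arrdc3, an arrestin-domain adaptor gene, had a log2 fold change of -1.47 (SE 0.231). Esyt3, a tether between the endoplasmic reticulum and the plasma membrane, stood at -1.98 (SE 0.252). Mlip and the prohormone convertase gene Pcsk2 stood at -2.04 and -1.89. The count of 88 was fragile: edgeR called 0 genes when any 1 control was left out (1532, 1766 and 2495 genes at an unadjusted p under 0.05), 640 without Pkm cKO replicate 1, 186 without replicate 2 and 125 without replicate 3. The same libraries gave 1118 genes with DESeq2, 2 with limma-voom, 2 with edgeR without robust estimation, and 57 higher against 18 lower with upper-quartile scaling.

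The enamel list had the lowest median of the 46 gene lists tested. Of its 18 measured members, 16 had a log2 fold change below 0, with a median of -1.13 (camera adjusted p 1.4e-06 and adjusted p 0.716 with an estimated correlation). The groups did not overlap for 10 of the 18, all lower in the cKO libraries, against 23.3% of all tested genes in either direction. Odam, a protein of ameloblasts and junctional epithelium, was the 1 member past the threshold over all genes and fell from 437 ± 18.4 to 186 ± 28.1 CPM (log2 fold change -1.23, SE 0.155, edgeR adjusted p 0.0312). Adjusted over the list alone, 3 members passed: Odam, the enamel surface protein gene Amtn (log2 fold change -1.84, under 1 CPM in both groups) and the integrin gene Itgb6 (-1.04, SE 0.296). Klk4, a protease of enamel maturation, had a log2 fold change of -1.99 (SE 0.711) and did not pass. The abundant matrix genes, chosen for mention after their values were seen, varied within groups and did not pass in the main test. Amelx, which encodes amelogenin, stood at 18617, 15596 and 8564 CPM in controls and at 4136, 343 and 122 CPM in cKO libraries. Enam, which encodes enamelin, had 3749, 3450 and 759 CPM against 378, 18.1 and 9.16 CPM. Ambn (ameloblastin) averaged 1767 ± 839 against 324 ± 368 CPM, Mmp20 (the enamel matrix protease) 212 ± 87.9 against 30.1 ± 42.3 CPM, and Acp4 (an acid phosphatase needed for enamel) 112 ± 45.5 against 15.5 ± 14.2 CPM. Without Pkm cKO replicate 1 Amelx (edgeR adjusted p 0.0245), Acp4 (0.0324) and Mmp20 (0.0477) passed, and with DESeq2 Acp4 (0.0161) and Enam (0.0350) did. Summed over the list, the libraries held 26587, 23290 and 11754 CPM in controls and 6494, 1695 and 846 CPM in the cKO group. Dspp, the main dentin matrix gene and a product mostly of odontoblasts, which are not epithelial, fell from replicate 1 to 3 within each group as the enamel sum did, but its groups overlapped, with 4617, 3497 and 1912 CPM against 2877, 588 and 112 CPM (log2 fold change -1.49, SE 1.25, not past the threshold).

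In all, 12 of the 46 lists passed camera's test with its preset correlation, 9 higher and 3 lower in cKO libraries. With a correlation estimated from the data, 0 of them passed, and each had an adjusted p of 0.716. On simulated counts a list of 20 genes raised 1.5-fold had a p of 2.6e-10 with the preset correlation and of 0.0455 with an estimated one, before adjustment over lists. Those counts were drawn independently for each gene, whereas the estimated correlations of the 12 lists ran from 0.15 to 0.95. The simulation therefore cannot tell which of these results holds for the real lists. With the preset correlation, 7 of the 10 splits of the 6 libraries into 3 and 3, the real one included, passed at least 12 lists. The highest other split passed 18. The number of lists passed with the preset correlation was thus not particular to the genotype groups. The self-contained test fry, which asks whether a list's genes moved on balance 1 way, passed 1 list, Wnt signaling (adjusted p 0.00266), which camera did not pass (adjusted p 0.110). The mixed form of fry, which asks whether a list's genes changed in either direction, passed 15 lists. Its lowest adjusted p belonged to the pyruvate and tricarboxylic acid list (0.00409) and the oxidative stress and NRF2 list (0.00675). Camera passed neither list (adjusted p 0.140 and 0.908).

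**Figure D2:**
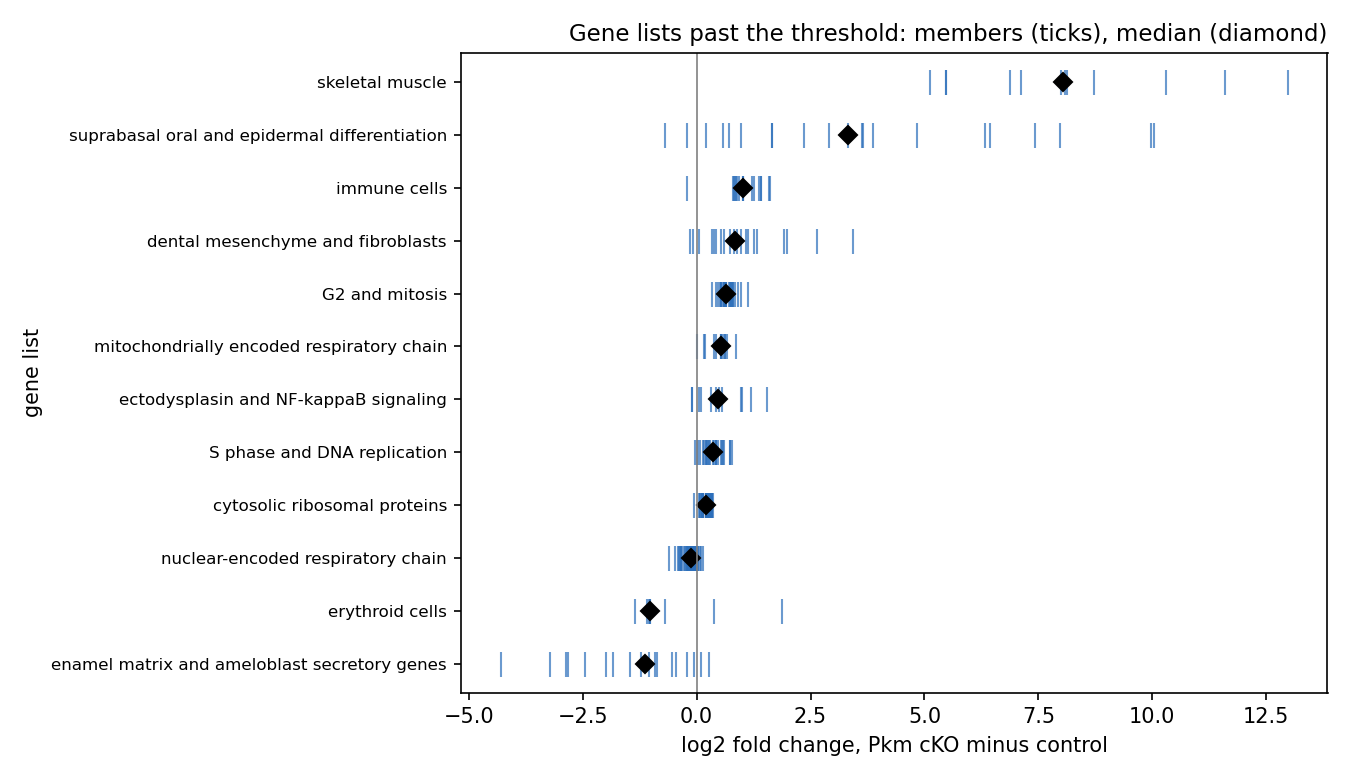
Log2 fold change (Pkm cKO minus control) of each measured member (tick) and the median (diamond) of the 12 gene lists past camera's threshold with the preset correlation. The enamel list had a median of -1.13 and the list of mitosis genes one of 0.65 with every member above 0. The fitted values of the skeletal muscle list rest on few control reads.

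Few genes of metabolism passed the threshold singly. Of the 20 measured genes of glycolysis and lactate export, 0 passed over all genes and 3 passed adjusted over the list alone. These were the glucose transporter gene Slc2a3 (log2 fold change 1.35, SE 0.363), the phosphofructokinase gene Pfkp (0.78, SE 0.214) and the monocarboxylate transporter gene Slc16a1 (-0.53, SE 0.156). The next by p, Gpi1, stood at 366 ± 54.0 CPM in controls and 521 ± 155 CPM in cKO libraries. The list as a whole, which holds Gapdh and Aldoa at uncertain levels, did not pass (median 0.17, camera adjusted p 0.519). The pentose phosphate (median -0.04, adjusted p 0.561), purine and pyrimidine (-0.21, 0.255), serine and one-carbon (0.45, 0.351) and pyruvate and tricarboxylic acid lists (-0.09, 0.140) did not pass either. The mixed form of fry passed the pyruvate and tricarboxylic acid (adjusted p 0.00409), purine and pyrimidine (0.0499) and fatty acid synthesis lists (0.0496). It did not pass the other lists of metabolism. Without Pkm cKO replicate 3 the median of the serine and one-carbon list was 0.19, that of the pentose phosphate list 0.01 and that of the fatty acid synthesis list -0.09. In the fatty acid synthesis list (median -0.16, camera adjusted p 0.127) the desaturase gene Scd1 (226 ± 32.0 against 133 ± 26.8 CPM) and the elongase gene Elovl6 (110 ± 17.0 against 70.8 ± 12.4 CPM) passed adjusted over the list alone. The nuclear-encoded respiratory chain list stood lower, with 35 of 41 members below 0 and a median of -0.12 (camera adjusted p 0.0124 and adjusted p 0.716 with an estimated correlation), though 0 members passed singly, adjusted over the list alone included. Ndufa1, a complex I subunit, had the lowest p among them (77.7 ± 6.13 against 50.9 ± 6.60 CPM). The 13 mitochondrially encoded genes of the same chain were all above 0, with a median of 0.53 (camera adjusted p 0.000946 and adjusted p 0.716 with an estimated correlation). Their share of all counts was 1.09% to 1.64% in controls and 1.79% to 2.45% in cKO libraries. None of them passed over all genes, and ND1, COX1 and COX2 passed adjusted over the list alone, ND1 with 1978 ± 438 CPM in controls and 3575 ± 726 CPM in cKO libraries. The level of COX2 is uncertain, since reads shared with other genes may have been left out. The nuclear list lost its call without control replicate 3 (median -0.05, adjusted p 0.201) and without Pkm cKO replicate 1 (-0.09, 0.0821), and the mitochondrial list without Pkm cKO replicate 3 (0.28, 0.0649).

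Of 3 lists of cell-cycle genes, 2 passed camera with the preset correlation. All 27 measured genes of G2 and mitosis had log2 fold changes above 0, with a median of 0.65 (camera adjusted p 1.5e-08 and adjusted p 0.716 with an estimated correlation). Of these, 0 passed over all genes and 11 passed adjusted over the list alone. Plk1, a kinase that drives mitotic entry, averaged 24.4 ± 4.98 CPM in controls and 53.6 ± 18.6 CPM in cKO libraries, Cdc20, an activator of the anaphase-promoting complex, 49.0 ± 12.3 against 96.9 ± 23.5 CPM, and Kif20a, a mitotic kinesin, 33.4 ± 5.29 against 54.9 ± 8.22 CPM. The S phase list was above 0 for 23 of 25 members (median 0.36, camera adjusted p 0.0234 and adjusted p 0.716 with an estimated correlation), 0 of which passed adjusted over the list alone. The groups overlapped in both summed lists: Pkm cKO replicate 1 had 667 CPM of the S phase list, below the 772 to 935 CPM of the controls, and 1230 CPM of the G2 and mitosis list, below the 1315 CPM of control replicate 3. The list of cyclins and cyclin-dependent kinase inhibitors did not pass (median 0.09, or 0.15 without Pkm cKO replicate 3, camera adjusted p 0.351). Mcm7, part of the replicative helicase, had the lowest p of the S phase list (78.3 ± 8.29 against 131 ± 29.4 CPM). Cytosolic ribosomal protein genes were above 0 for 31 of 32 members, with a median of 0.21 (camera adjusted p 0.00061 and adjusted p 0.716 with an estimated correlation) and 0 members past the threshold singly. The S phase list lost its call without control replicate 2 (median 0.26, adjusted p 0.125), Pkm cKO replicate 2 (0.22, 0.313) or Pkm cKO replicate 3 (0.17, 0.373), and the ribosomal list without control replicate 1 (0.12, 0.0694).

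Markers of other cells and tissues differed between the libraries. Genes of dental mesenchyme and fibroblasts were above 0 for 18 of 20 members (median 0.85, camera adjusted p 2.7e-06 and adjusted p 0.716 with an estimated correlation), with 0 past the threshold over all genes and 12 adjusted over the list alone. Among these were Barx1 (38.0 ± 5.83 against 66.9 ± 2.31 CPM) and Msx1 (30.1 ± 6.85 against 63.3 ± 13.4 CPM), transcription factors of tooth mesenchyme. Summed, the list held 31253, 32356 and 20710 CPM in controls and 41725, 24456 and 20886 CPM in cKO libraries. These sums overlapped between the groups, and mesenchymal transcripts were abundant in both. The most abundant members went differently: Col1a1 took 0.937% to 2.78% of all counts in the 6 libraries and had a log2 fold change of -0.09 (SE 0.388), Col1a2 one of -0.14 (SE 0.366), and Col3a1 one of 1.92 (SE 0.591), with 3374 CPM in Pkm cKO replicate 3 and 431 to 1054 CPM elsewhere. Immune cell genes were above 0 for 16 of 17 members, with a median of 1.02 (camera adjusted p 2.0e-07 and adjusted p 0.716 with an estimated correlation). The complement gene C1qc, made mainly by macrophages, rose from 7.34 ± 1.03 to 17.1 ± 0.746 CPM (log2 fold change 1.22, SE 0.214, edgeR adjusted p 0.0487) and was the 1 member past the threshold over all genes. Adjusted over the list alone, 9 passed, among them Csf1r, the receptor that sustains macrophages (15.4 ± 3.94 against 46.7 ± 15.8 CPM), and Laptm5 (10.3 ± 0.286 against 31.6 ± 12.9 CPM). Lyz2, a macrophage lysozyme, stood at 16.8 ± 2.18 and 14.5 ± 2.87 CPM. Erythroid genes were lower, with a median of -1.02 (camera adjusted p 0.00747 and adjusted p 0.716 with an estimated correlation). Hbb-bt, Hbb-bs (347 ± 76.0 to 164 ± 24.0 CPM) and Hba-a1 (202 ± 26.2 to 99.5 ± 18.7 CPM) fell over all genes, and 6 of 8 members passed adjusted over the list alone, 5 lower and 1 higher. The globin genes are near-identical copies, so reads may have been divided between them. The 13 endothelial genes had a median of 0.27 and did not pass (camera adjusted p 0.152), and without Pkm cKO replicate 3, which held 878 CPM of the list against 493 to 566 CPM elsewhere, the median was 0.02. The erythroid list lost its call without control replicate 3 (camera adjusted p 0.0503). Of the sex-linked genes, which were described and not tested as a list, 0 of 5 measured members passed edgeR's test. Their log2 fold changes were below 0 for 4 members, with a median of -0.91, or -1.40 without Pkm cKO replicate 3. They summed to 351, 616 and 182 CPM in controls and to 452, 487 and 424 CPM in cKO libraries. The list mixes Xist, which is expressed in females, with Y-linked genes of males. Its sums and median therefore do not show the sex of a library. Whether the sexes of the animals differed between the groups was not tested.

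Skeletal muscle and oral keratin genes were high in 1 library. The 12 measured muscle genes summed to 3922 CPM in Pkm cKO replicate 3, against 106 and 24.6 CPM in cKO replicates 1 and 2 and 6.04 to 7.90 CPM in the controls. Acta1, skeletal alpha-actin, had 769 CPM in that library, 41.7 and 8.37 CPM in the other cKO libraries and at most 1.03 CPM in controls. Myh3 and Myh8, the embryonic and perinatal myosin heavy chains, had 760 and 717 CPM there and at most 4.01 CPM elsewhere. The suprabasal oral and epidermal list summed to 7115 CPM in the same library and to 527 to 1037 CPM in the others. Krt13 and Krt4, keratins of the lining oral mucosa that were chosen for mention after their values were seen, reached 2831 and 1649 CPM there, against at most 18.3 and 8.17 CPM elsewhere. Both lists passed camera's test (adjusted p 1.4e-06 for muscle and 0.000338 for the suprabasal list), while 0 of their 12 and 21 members passed edgeR's test over all genes or adjusted over the list alone. With an estimated correlation each list had an adjusted p of 0.716. Without Pkm cKO replicate 3 the median log2 fold change went from 8.04 to 3.74 for the muscle list (camera adjusted p 1.0e-08) and from 3.32 to 0.90 for the suprabasal list (0.0119).

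**Figure D3:**
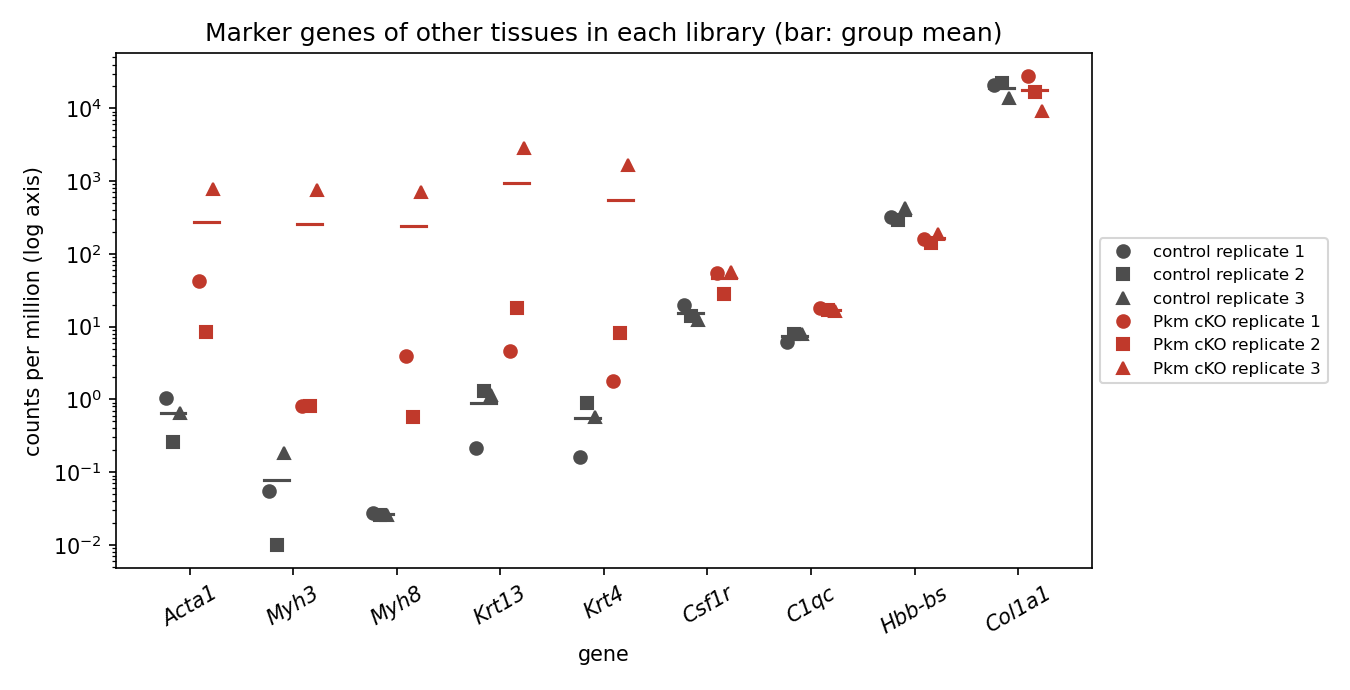
CPM (log axis) of marker genes of muscle (Acta1, Myh3, Myh8), oral mucosa (Krt13, Krt4), macrophages (Csf1r, C1qc), red cells (Hbb-bs) and mesenchyme (Col1a1) in each library, with controls in grey, Pkm cKO in red, bars at group means and the value of 0 for Myh3 in control replicate 2 drawn at 0.01. Pkm cKO replicate 3 reached 769 CPM for Acta1 and 2831 CPM for Krt13, and C1qc averaged 7.34 CPM in controls and 17.1 CPM in cKO libraries.

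Epithelial and signaling lists mostly did not pass. The list of basal epithelial keratins and identity had a median of -0.21 (camera adjusted p 0.0773). Cdh1, the epithelial cadherin, stood at 1123 ± 139 and 655 ± 37.5 CPM (log2 fold change -0.78, SE 0.149) and Krt14 at 2707 ± 528 and 1596 ± 353 CPM, and both passed adjusted over the list alone but not over all genes. In the junction list (median -0.09, adjusted p 0.0773) the genes that passed adjusted over the list alone included Cdh1, Lamb3 (log2 fold change -0.65, SE 0.183) and Lama3 (-1.16, SE 0.320), the last 2 of which encode laminin chains. The Wnt list, passed by fry, had 18 of 28 members above 0, and 4 passed adjusted over the list alone: Lgr6 (30.7 ± 4.91 against 59.4 ± 6.14 CPM), Nkd2 (20.4 ± 0.626 against 33.9 ± 2.15 CPM), Axin2 (56.5 ± 2.34 against 85.7 ± 7.40 CPM) and Sfrp1 (24.8 ± 3.05 against 63.9 ± 32.9 CPM). Lgr6 is an R-spondin receptor, Nkd2 and Axin2 are feedback inhibitors of the pathway and Sfrp1 is a secreted antagonist. In the FGF list (median 0.20, camera adjusted p 0.0773) the same adjustment passed Fgfr3 (log2 fold change 1.13, SE 0.215), Fgf10 (1.94, SE 0.418) and Fgf9 (1.17, SE 0.290) as higher and Fgf1 (-0.97, SE 0.254) as lower. The ectodysplasin and NF-kappaB list passed camera (median 0.47, adjusted p 0.0306, and adjusted p 0.716 with an estimated correlation) with 0 members past the threshold adjusted over the list alone. Its lowest p belonged to Edar, the ectodysplasin receptor (6.28 ± 1.35 against 14.3 ± 6.84 CPM), and its call was lost without control replicate 1 (adjusted p 0.0656) or Pkm cKO replicate 3 (0.218). Lists of hypoxia targets (median -0.29, adjusted p 0.0773), integrated stress response targets (0.24, 0.432), p53 targets (-0.04, 0.502), hedgehog (0.21, 0.125), BMP and TGF-beta (-0.10, 0.377) and Notch signaling (-0.09, 0.713) did not pass. Without Pkm cKO replicate 3 the medians of the p53, BMP and TGF-beta, and Notch lists were -0.15, -0.05 and -0.05.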

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

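Of the tests here, limma-voom with sample quality weights was chosen after the data were seen. Pkm was lower under every setting run, with log2 fold changes of -1.82 to -1.66 when libraries were left out in turn and edgeR adjusted p of 0.00867 to 0.0792. It missed the threshold without any 1 control and in the test against 1.5-fold (-1.74, adjusted p 0.0677). The counts of differing genes (88, 55 higher and 33 lower) ranged from 0 to 640 when libraries were left out, 0 to 317 higher and 0 to 323 lower. They were 518 (301 and 217) with no filter, 1118 (688 and 430) with DESeq2, 2 (0 and 2) with limma-voom, 2 (0 and 2) without robust estimation, and 230 (145 and 85) with quality weights. Against 1.5-fold they were 0 (0 and 0, 1069 at an unadjusted p under 0.05), with DESeq2 size factors 55 (16 lower), with upper-quartile scaling 18 lower, and without mitochondrial, hemoglobin and sex-linked genes 56 (17 lower). All 88 genes were among the 1118 of DESeq2 and 84 among the 230 with quality weights. DESeq2 also had the highest share of false calls in simulated counts, which gave both groups the same dispersion, unlike the real libraries. The cause of these shifts was not tested. Acp4, Enam, Amelx and Mmp20, which missed the threshold in the main test, passed it with quality weights (adjusted p 0.0345, 0.0345, 0.0387 and 0.0445), and some of them did so in other settings. Lists past the threshold numbered 9 to 18 with libraries left out, 0 with an estimated correlation and 1 with fry (15 in its mixed form), against 12. With the replicate number as a block, 708 genes (359 higher, 349 lower) and 15 lists passed. The deviations of libraries with the same number correlated at 0.235, 0.015 and 0.215, and those of libraries with unlike numbers at -0.278 to 0.070. Replicates 1 and 3 thus correlated best with their own number and replicate 2 did not. The labels do not say that the numbers mark pairs, so the main test left them out, and whether they do stays open. Genes whose direction turned with a library left out included Tuft1 (-0.20 to 0.10), Slc10a7 (-0.055 to 0.23), Tkt (-0.066 to 0.36) and Pgls (-0.071 to 0.25), none of them past the threshold, and the cause was not tested. Total counts were 30588350 or more per library, genes with few reads were not tested, and the effect of depth was not tested.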

Other observations

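Of the tests in this part, those of KEGG pathways and GO terms, the differences between list medians, the correlation across genes with the enamel score, the muscle and Pkm comparisons among libraries and the medians without Pkm cKO replicate 3 were chosen after the results were seen, as were the genes named with pathways and terms. Among 319 KEGG pathways taken from the table's annotation, protein processing in the endoplasmic reticulum had the lowest camera p (adjusted p 4.5e-06, and adjusted p 0.991 with an estimated correlation), with 130 of 159 members below 0 and a median log2 fold change of -0.21. Pdia3, a disulfide isomerase that folds glycoproteins, was its 1 member past edgeR's threshold and fell from 1461 ± 186 to 779 ± 45.5 CPM (SD, n = 3 each). Protein export, which holds the translocation machinery, had 23 of 27 members below 0 and a median of -0.37 (camera adjusted p 0.000393), and N-glycan biosynthesis a median of -0.26 (0.00596), each with adjusted p 0.991 with an estimated correlation. In all 20 pathways passed, 17 higher and 3 lower, 0 with an estimated correlation, and 2 without Pkm cKO replicate 3, protein processing (0.000179) and protein export (0.00428). The enamel list, which holds secreted products of ameloblasts, also had a median below 0, and whether the changes are linked was not tested.

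The 55 higher genes were enriched for the GO terms extracellular matrix organization, with 8 genes against 0.534 expected, and collagen trimer, with 6 against 0.217 (adjusted p 0.000141 for each, one-sided Fisher's exact test over 3838 terms). The 8 genes were Agt, Col13a1, Col8a2, Col9a2, Crispld2, Emilin1, Foxf2 and Mmp2. Mmp2, a gelatinase of stromal cells, rose from 109 ± 15.9 to 271 ± 75.0 CPM. The list of dental mesenchyme and fibroblast genes also had a median above 0 (0.85, with 18 of 20 members above 0). Whether the matrix terms reflect a different mixture of cells or a change within the epithelium was not tested. Ossification held 6 higher genes (adjusted p 0.00196), among them Bmp6, Csf1 and Pth1r. The lower genes were enriched for oxygen binding (adjusted p 0.00408) through Hba-a1, Hbb-bs and Hbb-bt. Without Pkm cKO replicate 3 oxygen binding had 2 genes and an adjusted p of 0.804, so its call was lost, while extracellular matrix organization (8.7e-08), collagen trimer (8.7e-08) and ossification (0.0136) still passed. Only that library was left out for the terms. With any 1 control left out, with limma-voom or without robust estimation, 0 higher genes were called, so no term over them could pass.

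The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 88 genes and the highest other split 0, so that 1 split reached the count. For gene lists the real split gave 12 and the highest other split 18, and 7 of the 10 splits gave at least as many.

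The enamel list had a median log2 fold change of -1.13 (camera adjusted p 1.4e-06 with the preset correlation, 0.716 with an estimated one, and 0.217 by fry), and its genes spread within the cKO group. A smaller share of epithelial cells that lowers all epithelial genes alike is argued against, as the whole cause, by the basal epithelial list. That list summed to 15793, 13676 and 14475 CPM in controls and 9747, 11525 and 10637 CPM in cKO libraries. The enamel list went from 26587, 23290 and 11754 to 6494, 1695 and 846 CPM, a larger fall in Pkm cKO replicates 2 and 3 above all. The enamel median minus the basal median was -0.92 (95% bootstrap interval over genes, not libraries, -1.99 to -0.32). Without Pkm cKO replicate 3, which held oral keratin genes, the medians were -0.94 and -0.28. Both medians were known before they were compared. The basal genes are not particular to the tooth, so oral epithelium carried into a library would add to them. The suprabasal list summed to 527 and 1037 CPM in Pkm cKO replicates 1 and 2, against 615 to 691 CPM in controls. A smaller share of dental epithelium, with other epithelium carried in, therefore stays open. A difference in tooth stage or dissection apart from genotype cannot be told apart from an effect of the deletion. Across genes, which are not independent replicates, the difference between controls 3 and 1 correlated at r = 0.299 with that between the cKO mean and control 2, a pair of contrasts that share no library, and the enamel score ranged over 0.80 among controls against a group difference of 1.73. The labels give no litter or hour, so an effect of the deletion and a stage difference between litters both stay open.

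The skeletal muscle and keratin genes were high in Pkm cKO replicate 3: all 12 muscle genes, and 10 of 21 genes of the suprabasal list, lay at least 10-fold above the next highest library. This count restates what drew attention to the library, so it does not test whether muscle and oral mucosa were carried into it, which stays open. An effect of the deletion alike in every cKO library is argued against by the summed muscle CPM, which differed 159.7-fold among them. A control library under this label is argued against by Pkm, at 350 CPM against at least 1049 CPM in controls. An unrelated library cannot be weighed this way, because its level of Pkm is not known. Cell mixtures were not measured otherwise, and the smaller muscle signal of the other cKO libraries (106 and 24.6 CPM against at most 7.90 CPM in controls) stays open.

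The lists of mesenchymal and immune cell genes had medians above 0 (0.85 and 1.02, camera adjusted p 2.7e-06 and 2.0e-07, and adjusted p 0.716 for each with an estimated correlation). Of their members 0 and 1 passed over all genes, and Lyz2, Col1a1 and Col1a2 had log2 fold changes below 0. The summed CPM of the mesenchymal list overlapped between the groups. A lower share of epithelial cells that raises every other type alike is argued against by lists that moved apart. The immune list summed to 96.7, 102 and 96.9 CPM in controls and 250, 150 and 252 CPM in cKO libraries. The erythroid list, which holds near-identical globin copies, went from 680, 576 and 807 CPM to 356, 269 and 357 CPM. The immune median exceeded the erythroid median by 2.04 on the log2 scale (95% bootstrap interval over genes 0.64 to 2.39). It exceeded the endothelial median by 0.75 (0.58 to 1.10). These medians were known before they were compared, and the intervals do not measure the spread between libraries. The endothelial median of 0.27 was 0.02 without Pkm cKO replicate 3. Tissue carried into Pkm cKO replicate 3 alone is argued against by the medians without that library, 0.66 for mesenchyme and 0.99 for immune cells. More immune cells, a different kind of mesenchyme around the tooth, a different amount of blood, and a response to the deletion all stay open and were not tested.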
